A study of Homo sapiens with 6 samples.

How the data were processed

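Polyadenylated RNA of 6 LNCaP libraries was measured, 3 untreated and 3 treated with doxycycline, prepared with a KAPA mRNA kit per the labels' protocols. Reads were aligned with STAR 2.7.2 to hg38 and quantified with RSEM, per the submitters' processing notes. The RSEM version, the annotation release and the strand setting were not given in the sources used here. The authors deposited 1 gene table per library with 60668 genes. Per the file headers, each table holds an expected count, TPM, FPKM, a transcript length and an effective length per gene. The deposited expected counts are RSEM's estimates, which share reads that match several genes or isoforms between them, and 17.5 to 18.5% of genes with a count in a library had a value that was not whole within 0.001. TPM and FPKM in the deposited tables are scaled for effective length and depth by RSEM. The deposited length is the mean over a gene's transcripts weighted by their estimated abundance, and the effective length corrects it for fragment length.

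Groups were taken from the labels. Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr (minimum count 10), which left 15559 genes holding 99.9% of counts. These were tested with edgeR 4.0.16 (TMM factors, quasi-likelihood fit and test, R 4.3.3), with Benjamini-Hochberg adjusted p under 0.05 as threshold. CPM values use the TMM-scaled library sizes, and log2 CPM a prior count of 2. Mean fragment length was estimated per library as the median difference between length and effective length for genes above 2000 nt. Library totals of 24183015 to 34120603 expected counts set the precision, and the biological coefficient of variation was 0.0985.

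A total of 33 gene lists with 853 distinct members were fixed before the data were examined, and 3 of their symbols were not found. The 31 lists with at least 5 tested members were tested with limma 3.58.1 camera on log2 CPM with a preset correlation of 0.01, and again with an estimated correlation, two-sided, adjusted over the 31 lists. The estimated form also rests on the few residual degrees of freedom of 6 libraries, which lowers its power whatever the correlation. Transcript lengths were tested with limma on log2 length, with a trend, for genes with more than 1 transcript and an expected count of at least 50 in every library.

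The genes named were set by a rule fixed at the same time: PRMT1, the 10 largest rises and falls among genes past 0.05 with a mean of at least 5 CPM and groups that do not overlap, the 5 smallest p-values in each direction among the rest, the 2 smallest p-values of each list in each direction, all members of the PRMT family and of lists with up to 5 tested members, and the 5 largest length changes in each direction. Some genes that the rule or a list covers are not reported here. Genes known only by a clone name were treated as having no symbol and passed over. Other list members are named where a count was 5 or fewer, and those were chosen after their values were seen. Coordinates, gene types, overlaps and genomic spans came from GENCODE 29 on GRCh38, the same assembly but a release that may differ from the authors', and 98.97% of tested genes matched by identifier.

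The count and list steps were tested on simulated counts drawn gene by gene from the means and library sizes of this comparison. The length step used the mean lengths of these data with independent noise added. Neither holds correlation between genes or a fragment length effect, so false calls in the real data may be more frequent. With 15360 genes, edgeR recovered 3 of 50 genes changed 1.2-fold, 27 of 50 changed 1.5-fold, 44 of 50 changed 2-fold and 48 of 50 changed 4-fold. It made 14 false calls, 10.3% of its calls and above the nominal 5%. Only 50 genes were changed at each size, against 4396 genes past the threshold in the real data. The Benjamini-Hochberg threshold is stricter where fewer genes change, so these recoveries and this share of false calls need not hold for the real comparison. Camera found the shifted list (adjusted p = 3.23e-28, and adjusted p = 0.00724 with an estimated correlation) and 0 others. With 10900 genes, the length test recovered 22 of 40 genes changed by 0.5 on the log2 scale and made 2 false calls.

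Alternatives were DESeq2 1.42.0, limma-voom, other scalings and count filters, length offsets, limma on TPM, the replicate number as a block, each library left out, stricter thresholds, fry and cameraPR in place of camera, and other settings of the length test. Fragment length as a covariate, and estimated correlations with that covariate or with the block, were added after seeing the data. Figures were drawn with matplotlib 3.10.9. FPKM values were not used in any test.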

Results

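RNA was sequenced from 6 libraries of LNCaP cells, a human prostate cancer line that responds to androgen. The cells carried a short hairpin RNA against PRMT1 whose expression is switched on by doxycycline. PRMT1 is the main enzyme that places asymmetric dimethyl marks on arginines of histones and RNA-binding proteins. There were 3 untreated control libraries and 3 libraries from cells given 100 ng/mL doxycycline over 7 days, called PRMT1 knockdown here. Expected counts summed to 28215908, 29913271 and 24183015 in control libraries 1 to 3 and to 27717072, 34120603 and 25676668 in knockdown libraries 1 to 3. A count of 3, used as a detection floor, equalled 0.0879 to 0.124 CPM, and this floor covers counting error only. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries only. No library with doxycycline and without the hairpin was analysed here, so each difference below is between treated and untreated hairpin cells.

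The first question was whether the targeted transcript was reduced in the treated libraries. PRMT1 (ENSG00000126457.21, hg38 chromosome 19, 49675786 to 49689029) averaged 66.7 ± 0.533 CPM in control and 24.99 ± 0.646 CPM in knockdown libraries (SD, n = 3 each). The log2 fold change was -1.42 (SE 0.077, edgeR adjusted p = 9.31e-06), and every knockdown library lay below every control library. Of the 7 other tested members of the arginine methyltransferase family, 2 rose: PRMT5, the main symmetric dimethyltransferase, by 0.33 (SE 0.061, edgeR adjusted p = 0.00419) and CARM1 by 0.27 (SE 0.079, edgeR adjusted p = 0.0287). The others did not pass 0.05, with log2 fold changes of -0.21 for PRMT2, -0.14 for PRMT6, -0.10 for PRMT3, -0.08 for PRMT9 and 0.10 for PRMT7. As a list the family did not pass camera (adjusted p = 0.712). When adjusted over the list alone, 2 members rose and 1 fell. CARM1 did not pass with library size only or upper quartile factors, and with library size only 1 member rose and 3 fell, PRMT1, PRMT2 and PRMT6. PRMT7 turned negative when counts were scaled by library size only or taken as TPM, PRMT2 turned positive with length offsets, PRMT3 turned positive without control library 3 or knockdown library 2, and PRMT9 without control library 3 or knockdown library 3.

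**Figure D1:**
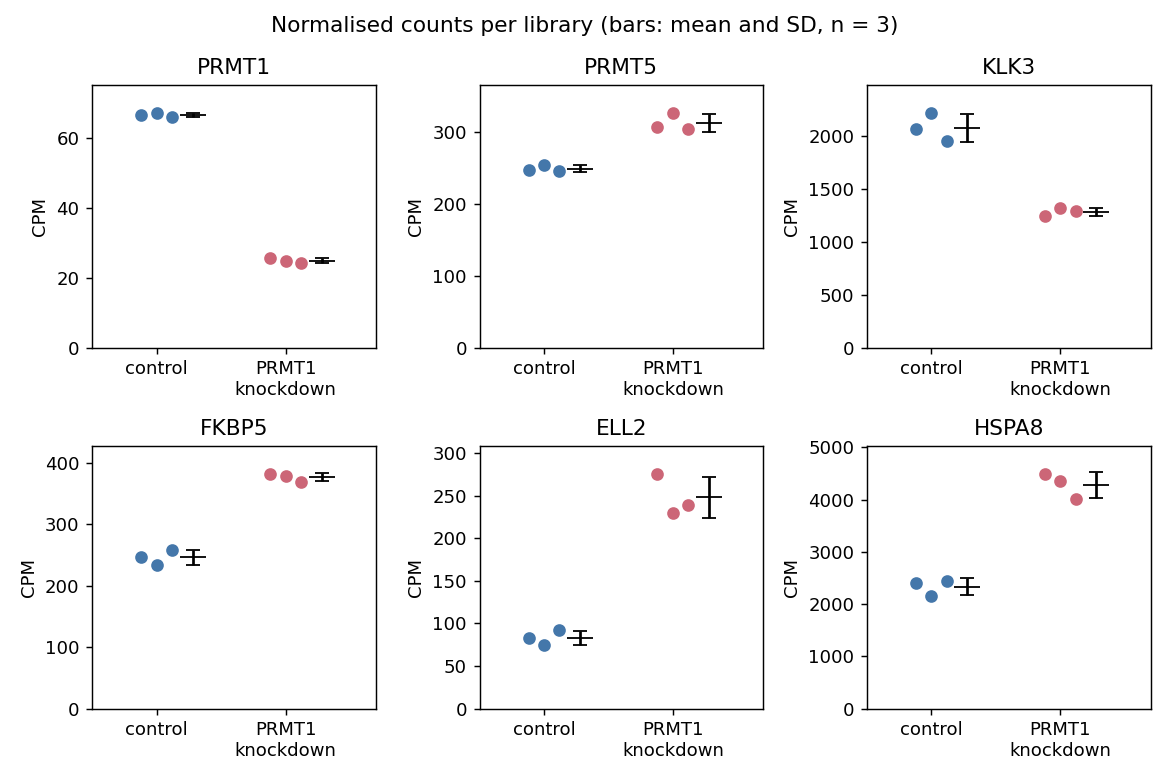
CPM (counts scaled by the TMM-adjusted library size, vertical axes from 0) in each of the 3 control and 3 PRMT1 knockdown libraries for 6 genes, with the group mean and SD beside the points. PRMT1 falls from 66.7 to 24.99 CPM and KLK3 from 2082 to 1288 CPM, while PRMT5, FKBP5, ELL2 and HSPA8 are higher.

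Across the transcriptome, the knockdown libraries differed from control in 4396 of 15559 tested genes, of which 1939 were higher and 2457 lower (edgeR quasi-likelihood test, adjusted p under 0.05). Large falls outnumbered large rises, with 655 genes lower and 156 higher by at least 1 on the log2 scale. The largest falls among genes with a mean of at least 5 CPM were in GRK1, a G protein-coupled receptor kinase (log2 fold change -2.85, SE 0.13, from 25.4 ± 3.01 to 3.52 ± 0.324 CPM, n = 3 each), CCDC92 (-2.80), GNG4 (-2.21), the non-coding LINC01137 (-2.15) and HDAC4, a class IIa histone deacetylase (-2.05). RPS6KA2 (-1.98), LRP11 (-1.97), the organic cation transporter SLC22A3 (-1.94), KIAA1257 (-1.90) and BCL11B (-1.75) followed. The largest rises were in DGCR11 (1.95), AGR2, a protein disulfide isomerase of secretory epithelia (1.92, SE 0.12, from 6.10 ± 0.733 to 23.0 ± 1.78 CPM, n = 3 each), the transporter SLC16A6 (1.68), CD68 (1.60) and the elongation factor ELL2 (1.58). TMEM147-AS1 (1.43), CECR7 (1.43), UGT2B10 (1.41), ZNF8-ERVK3-1 (1.31) and the transferrin receptor TFRC (1.29) were next. The 5 smallest p-values among the remaining genes belonged to MOCOS, ATP11A, COL4A5, KLHL35 and INPP5A for falls of -1.27 to -1.68, and to DUSP4, the mitochondrial ribosomal RNA MT-RNR1, GPR158, ODC1 and ADAMTS1 for rises of 0.77 to 1.27. INPP5A transcripts were also shorter in the knockdown libraries (log2 length change -0.46), so its fall in count need not mean fewer transcripts. Groups did not overlap in 4335 of the changed genes and in 43.4% of all tested genes, where chance alone gives 10%.

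Several of these genes may share reads with neighbours or relatives, and the strand setting of the counting was not given in the sources used here. DGCR11 lies inside DGCR2, ZNF8-ERVK3-1 spans ZNF8 and ERVK3-1, and PRMT1 overlaps ADM5 on the same strand. TMEM147-AS1 is antisense to TMEM147, CCDC92 overlaps DNAH10 and ZNF664 on the opposite strand, SLC16A6 overlaps ARSG, KIAA1257 overlaps ACAD9 and EFCC1, RPS6KA2 overlaps an antisense RNA, and CECR7 is an annotated pseudogene. UGT2B10 and UGT2B11 have near-identical relatives. The split between higher and lower genes moved with the scaling of the libraries. Of the changed genes, 44.1% were higher with TMM factors, 47.8% with DESeq2 size factors in edgeR, 19.9% with library size only and 30.9% with upper quartile factors. Library size only lowered the median of all log2 fold changes by 0.116. Where the test or the filter differed as well, 54.6% were higher with DESeq2, and 17.9% and 17.8% with limma on TPM with pseudocounts of 1 and 0.1.

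The first principal component of log2 CPM held 53.8% of the variance and separated the groups. The second, with 19% of the variance, followed the mean fragment length, which was 227, 192.4 and 225.2 nt in control libraries 1 to 3 and 231.8, 208.6 and 201.8 nt in knockdown libraries 1 to 3. The group means were 214.9 and 214.1 nt. Within the long-fragment libraries (control 1 and 3, knockdown 1) PRMT1 differed by -1.37 and within the short-fragment ones (control 2, knockdown 2 and 3) by -1.44 on the log2 scale. Each set holds a group with 1 library and gives no test. The count of changed genes was 2386 without control library 1, 2618 without knockdown library 2 and 2597 without knockdown library 3, and 7839 with fragment length as a covariate chosen after seeing the data.

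**Figure D2:**
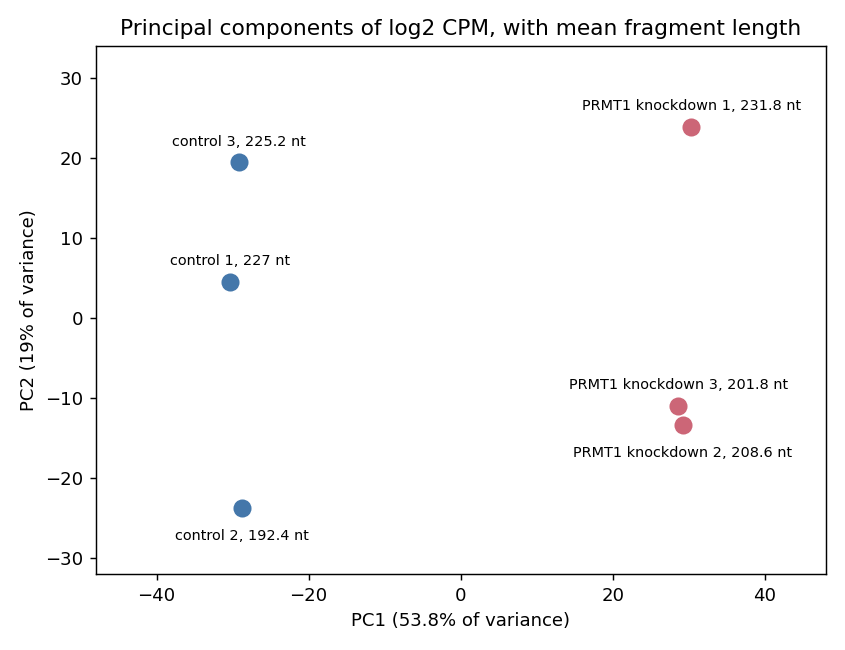
First and second principal components of log2 CPM for the 6 libraries, each marked with its group, replicate and mean fragment length in nucleotides (nt). Control and knockdown libraries separate along the horizontal axis, and along the vertical axis the 3 libraries with fragments of 225.2 to 231.8 nt lie above the 3 with 192.4 to 208.6 nt.

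A second question was how androgen-regulated genes behaved, since LNCaP cells depend on androgen. Of 43 tested genes that androgen induces, 18 fell and 7 rose. KLK3, which encodes prostate-specific antigen, fell by 0.69 on the log2 scale (SE 0.059, edgeR adjusted p = 8.21e-05, 2082 ± 133 to 1288 ± 38.6 CPM, n = 3 each). In the opposite direction, FKBP5, a co-chaperone of steroid receptors, rose by 0.61 (SE 0.063) and ELL2 by 1.58 (SE 0.099). The median of the list was -0.17 and camera did not pass (adjusted p = 0.149, and adjusted p = 0.336 with an estimated correlation). It was past 0.05 with fry (adjusted p = 0.00443), which does not compare the list with other genes, and with cameraPR (adjusted p = 0.0287). When adjusted over the list alone, 18 fell and 8 rose.

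Among 15 tested androgen-repressed genes, the glucuronosyltransferases UGT2B10 (1.41), UGT2B11 (0.82) and UGT2B28 (0.70) rose, while DDC (-1.27), FOLH1, which encodes prostate-specific membrane antigen (-0.68), BCHE (-0.58) and ACKR3 (-0.27) fell. Camera did not pass for this list (adjusted p = 0.656), and adjusted over the list alone 3 rose and 5 fell. Of 20 nuclear receptor cofactors, 4 rose (HSP90AA1 by 0.78, FKBP4 by 0.52, NCOA1 by 0.23 and KDM1A by 0.22) and 3 fell: the lineage factor HOXB13 by 0.60, the histone methyltransferase NSD2 by 0.41 and the pioneer factor FOXA1 by 0.27 on the log2 scale. Camera did not pass (adjusted p = 0.365), with the same counts adjusted over the list alone, and with library size only 2 rose and 6 fell. The NSD2 count change was 0.03 (edgeR adjusted p = 0.745) once transcript lengths entered as offsets, and its transcripts were also shorter in the knockdown libraries.

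Genes of ribosome production rose more often than they fell. Of 35 MYC targets and ribosome biogenesis genes, 29 rose and none fell, 31 when adjusted over the list alone and 19 with library size only, with a median log2 fold change of 0.38 (camera adjusted p = 9.35e-11, adjusted p = 0.0395 with an estimated correlation, but adjusted p = 0.197 with that correlation and fragment length in the model). Nucleolin, NCL, rose by 0.45 (SE 0.049, 1543 ± 44.1 to 2111 ± 52.7 CPM, n = 3 each) and PA2G4 by 0.44 (SE 0.054). Of 71 cytosolic ribosomal protein genes, 33 rose and none fell, 42 adjusted over the list alone, with smaller changes (median 0.19, camera adjusted p = 1.86e-09, but adjusted p = 0.377 with an estimated correlation). RPL24 rose by 0.38 and RPL26 by 0.27. With library size as the only scaling, 5 of the 71 rose.

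Replication genes were also higher. Of 38 genes of G1/S and DNA replication, 24 rose and none fell, 27 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 5.85e-09, but adjusted p = 0.336 with an estimated correlation). RFC5, a clamp loader subunit, rose by 0.65 (SE 0.084) and the phosphatase CDC25A by 0.63 (SE 0.084), while CDC45 (-0.15) and RFC3 (-0.24) did not pass. Of 35 genes of G2/M and mitosis, 12 rose, among them CCNA2 by 0.64 and CDC20 by 0.40, and 1 fell, CENPA by 0.31 on the log2 scale (camera adjusted p = 0.000445, but adjusted p = 0.426 with an estimated correlation). Adjusted over the list alone, 13 rose and 1 fell, PRC1 was at -0.05, and with library size only 2 rose and 1 fell. Of 13 tested replication-dependent histone genes, 4 fell: HIST1H2BG (-0.77), HIST1H2BC (-0.63), HIST2H4A (-0.56) and HIST2H2BE (-0.36), also 4 adjusted over the list alone. The list passed camera in the downward direction (adjusted p = 0.0268, but adjusted p = 0.336 with an estimated correlation). HIST1H2BK (0.23) and HIST1H2AC (0.00) did not pass. These genes have near-identical copies, and their transcripts mostly lack the poly(A) tail on which the libraries were selected.

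Chaperone genes rose, with 15 of 18 heat shock response genes higher and none lower, also 15 adjusted over the list alone (median 0.44, camera adjusted p = 1.74e-06, but adjusted p = 0.0643 with an estimated correlation). HSPA8, the constitutive HSP70, rose by 0.88 (SE 0.065, 2332 ± 163 to 4285 ± 249 CPM, n = 3 each) and HSP90AA1 by 0.78 (SE 0.081). The strongly stress-inducible HSPA1A (-0.60) and HSPA6 (-0.63) did not pass (edgeR adjusted p = 0.251 and 0.199). HSPA1B, which is nearly identical to HSPA1A, rose by 0.36, and reads shared between these genes leave both counts uncertain.

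Mitochondrial transcripts were higher. Of 13 mitochondrially encoded mRNAs, 11 rose and none fell, 12 adjusted over the list alone, with a median of 0.49 (camera adjusted p = 1.74e-06, but adjusted p = 0.0643 with an estimated correlation). MT-ND2 rose by 0.70 (SE 0.061) and MT-ND5 by 0.69 (SE 0.057). Mitochondrial genes held 2.25 ± 0.04% of counts in control and 2.78 ± 0.056% in knockdown libraries (SD, n = 3 each). Of 43 nuclear genes of the respiratory chain, 9 rose, among them COX5A by 0.29 and ATP5F1B by 0.25, and UQCRFS1 fell by 0.38 on the log2 scale (median 0.15, camera adjusted p = 0.000802, but adjusted p = 0.336 with an estimated correlation). The counts were the same adjusted over the list alone, and SDHC was at -0.07. With library size only the median was 0.03, 1 of the 43 fell and the 9 rises did not pass.

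Lipid and glucose metabolism genes moved mainly upward. Of 23 cholesterol synthesis genes, 11 rose and none fell, 15 adjusted over the list alone (camera adjusted p = 2.47e-05, but adjusted p = 0.0643 with an estimated correlation), including INSIG1 by 0.75 (SE 0.085) and FDFT1, squalene synthase, by 0.54 (SE 0.058). PMVK (-0.18) and HSD17B7 (-0.04) did not pass. Of 16 fatty acid synthesis genes, 9 rose, among them fatty acid synthase FASN by 0.85 (SE 0.078) and SCD by 0.48 (SE 0.073), and 2 fell, ELOVL2 by 1.04 and ACACB by 0.58 on the log2 scale (camera adjusted p = 0.0478, but adjusted p = 0.336 with an estimated correlation). Adjusted over the list alone, 9 rose and 3 fell. Of 28 hypoxia and glycolysis genes, 15 rose, including CA12 by 0.95 (SE 0.077) and GAPDH by 0.35 (SE 0.051), and the phosphofructokinase PFKP fell by 0.82 on the log2 scale (camera adjusted p = 1.27e-05, but adjusted p = 0.336 with an estimated correlation). Adjusted over the list alone, 16 rose and 1 fell. VEGFA was at -0.07 and turned positive without knockdown library 2.

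Of 20 genes of the methionine cycle and polyamines, ODC1, which makes putrescine, rose by 0.77 (SE 0.056, 742 ± 30.9 to 1264 ± 43.6 CPM, n = 3 each), AMD1 by 0.84, SRM by 0.55, MTRR by 0.39 and MAT2A by 0.24, while PAOX fell by 1.10, GNMT by 0.50 and MTR by 0.29 on the log2 scale. Camera did not pass (adjusted p = 0.493), and adjusted over the list alone 5 rose and 4 fell, and with library size only 3 rose and 6 fell. Of 30 genes of the ATF4 and amino acid response, 11 fell and GDF15 rose by 0.30. The transporter SLC7A5 fell by 0.95 (SE 0.089) and the pseudokinase TRIB3 by 0.72 (SE 0.086) on the log2 scale. The list did not pass camera (adjusted p = 0.0636, and adjusted p = 0.503 with an estimated correlation), CHAC1 was at 0.32, and adjusted over the list alone 12 fell and 2 rose. With library size only 16 fell and none rose, and with upper quartile factors 12 fell and none rose. Of 22 ER stress genes, HSPA5 (0.28), CANX (0.27) and CALR (0.18) rose and none fell (camera adjusted p = 0.49). HYOU1 (-0.21) and XBP1 (-0.18) did not pass, and 2 rose adjusted over the list alone. With library size only none of the 22 rose and 6 fell, and with upper quartile factors 2 rose and 5 fell.

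Splicing factor genes rose more often than they fell. Of 45 hnRNP and SR genes, 19 rose, among them RBM3 by 0.56 (SE 0.057) and SRSF2 by 0.39 (SE 0.060), and 2 fell, among them CIRBP by 0.34 on the log2 scale (camera adjusted p = 2.61e-05, but adjusted p = 0.271 with an estimated correlation). Adjusted over the list alone, 22 rose and 2 fell, and with library size only 5 rose. Of 20 nonsense-mediated decay and autoregulated transcripts, 3 rose, among them SMG5 (0.48) and UPF1 (0.23), and GADD45A (-0.34) fell, while CLK4 was at -0.33 (camera adjusted p = 0.149). Adjusted over the list alone, 2 rose and 1 fell, and with library size only 1 rose and 2 fell.

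The p53, apoptosis and MAPK lists held changes in both directions. Of 26 p53 targets, 6 rose, led by the cell cycle inhibitor CDKN1A by 0.84 (SE 0.094) and PLK3 by 0.72, and DDB2 (-0.70), RRM2B (-0.47) and SESN1 (-0.33) fell (camera adjusted p = 0.217, the same counts adjusted over the list alone, but 4 higher and 6 lower with library size only and 4 each with upper quartile factors). Of 22 apoptosis regulators, 4 rose, among them BMF (0.998), BCL2L11 (0.43) and BIK (0.42), and BCL2L2 (-0.62), BCL2 (-0.54), BID (-0.41) and BOK (-0.39) fell (camera adjusted p = 0.41, the same counts adjusted over the list alone, but 2 higher and 5 lower with library size only). Of 26 homologous recombination genes, FANCA (0.49), CHEK1 (0.38) and RAD54L (0.26) rose (camera adjusted p = 0.323), 1 when adjusted over the list alone, and FANCD2 (-0.21) and TP53BP1 (-0.20) did not pass. With library size only 1 rose and 2 fell, and with upper quartile factors 2 rose and 2 fell. Of 19 MAPK immediate early genes, 6 rose, with the phosphatase DUSP4 at 1.27 (SE 0.065) and JUNB at 0.93, and FOSB (-1.55) and SPRED1 (-0.50) fell (camera adjusted p = 0.0843). Adjusted over the list alone, 7 rose and 2 fell, and with library size only or upper quartile factors 3 rose and 2 fell.

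Of 32 interferon response genes, OAS1 (1.73, from 0.469 to 1.56 CPM), SAMD9 (1.24), IRF7 (0.70), ISG15 (0.53) and HERC6 (0.36) rose and CMPK2 (-0.63), IFIH1 (-0.59) and DTX3L (-0.34) fell (camera adjusted p = 0.338), but 2 rose and 5 fell with library size only. Of 8 NF-kB inflammatory genes, NFKBIA (0.39) rose and TNFAIP2 (-0.45) fell, and NFKB2 (0.24) and SOD2 (-0.20) did not pass (camera adjusted p = 0.415), and with library size only 1 rose and 3 fell. Of 25 autophagy and lysosome genes, 6 rose, with the smallest p-values for NPC1 (0.57) and ATG9A (0.36), and none fell (camera adjusted p = 0.0794), while GAA (-0.14) and CTSB (-0.13) did not pass. For these 3 lists the counts adjusted over the list alone were the same as over all genes.

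The luminal, basal and mesenchymal lists held changes in both directions. Of 18 luminal epithelial genes, ELF3 (0.80), CLDN4 (0.50), ESRP2 (0.48), CDH1 (0.27) and KRT18 (0.26) rose and CD24 (-0.83) and ESRP1 (-0.69) fell (camera adjusted p = 0.215). Among these 18, 4 rose and 3 fell with library size only, and 4 rose and 2 fell with upper quartile factors. Of 7 tested basal genes, KRT14 (-0.80), ITGB4 (-0.69), DST (-0.48) and LAMA3 (-0.31) fell and LAMB3 (0.87) rose, and TRIM29 was at 0.09 and turned negative with library size only, length offsets or TPM (camera adjusted p = 0.215). Of 12 mesenchymal and fibroblast genes, PDGFRB (-1.40), ACTA2 (-0.96), COL6A2 (-0.37) and COL6A1 (-0.30) fell and FN1 (0.19) rose, though not with library size only or upper quartile factors, with SPARC at 0.55 (camera adjusted p = 0.493). Of 6 tested neuroendocrine genes, POU3F2 (-1.55, from 0.599 to 0.195 CPM) fell, and SYP (-0.54) and ONECUT2 (0.32) did not pass (camera adjusted p = 0.493). For these 4 lists the counts adjusted over the list alone were the same as over all genes. Of 15 leukocyte and endothelial markers, 2 were abundant enough to test: CD68, also a lysosomal protein of many cells, rose by 1.60 and VWF fell by 0.76 on the log2 scale. The 3 tested markers of other prostate cancer lines, VIM (0.19), CCN1 (0.09) and LGALS1 (-0.24), did not pass. The last 2 lists were too short for camera, and adjusted over each list alone the counts were the same.

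Of 31 lists tested, 12 passed camera with its preset correlation, 11 upward and 1 downward, and 1 passed with an estimated correlation, but 0 with that correlation and either fragment length or the replicate number in the model. The added terms leave still fewer degrees of freedom, so a list lost there is not shown to follow fragment length. Nor is correlation always the reason: MYC targets had an estimated correlation of -0.00493, yet the camera p went from 3.02e-12 to 0.00127. For cytosolic ribosomal proteins the estimate was 0.305. Other splits of the 6 libraries into groups of 3, which all mix control and knockdown libraries, gave 4 to 11 lists with the preset correlation and none with the estimated one. With library size only, the lists of p53 targets, apoptosis regulators, nuclear receptor cofactors, ER stress, homologous recombination, interferon response, autophagy, the methionine cycle and the markers of other prostate lines had medians below 0, where TMM factors gave medians above 0. The medians of the 12 lists past camera kept their sign under TMM, DESeq2, upper quartile and library size scaling. Camera compared each list with all other tested genes, and no list was matched on abundance. Coding genes matched to the CPM of the long non-coding genes described below had a median log2 fold change of -0.249. Whether abundance contributes to the upward lists was not tested.

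**Figure D3:**
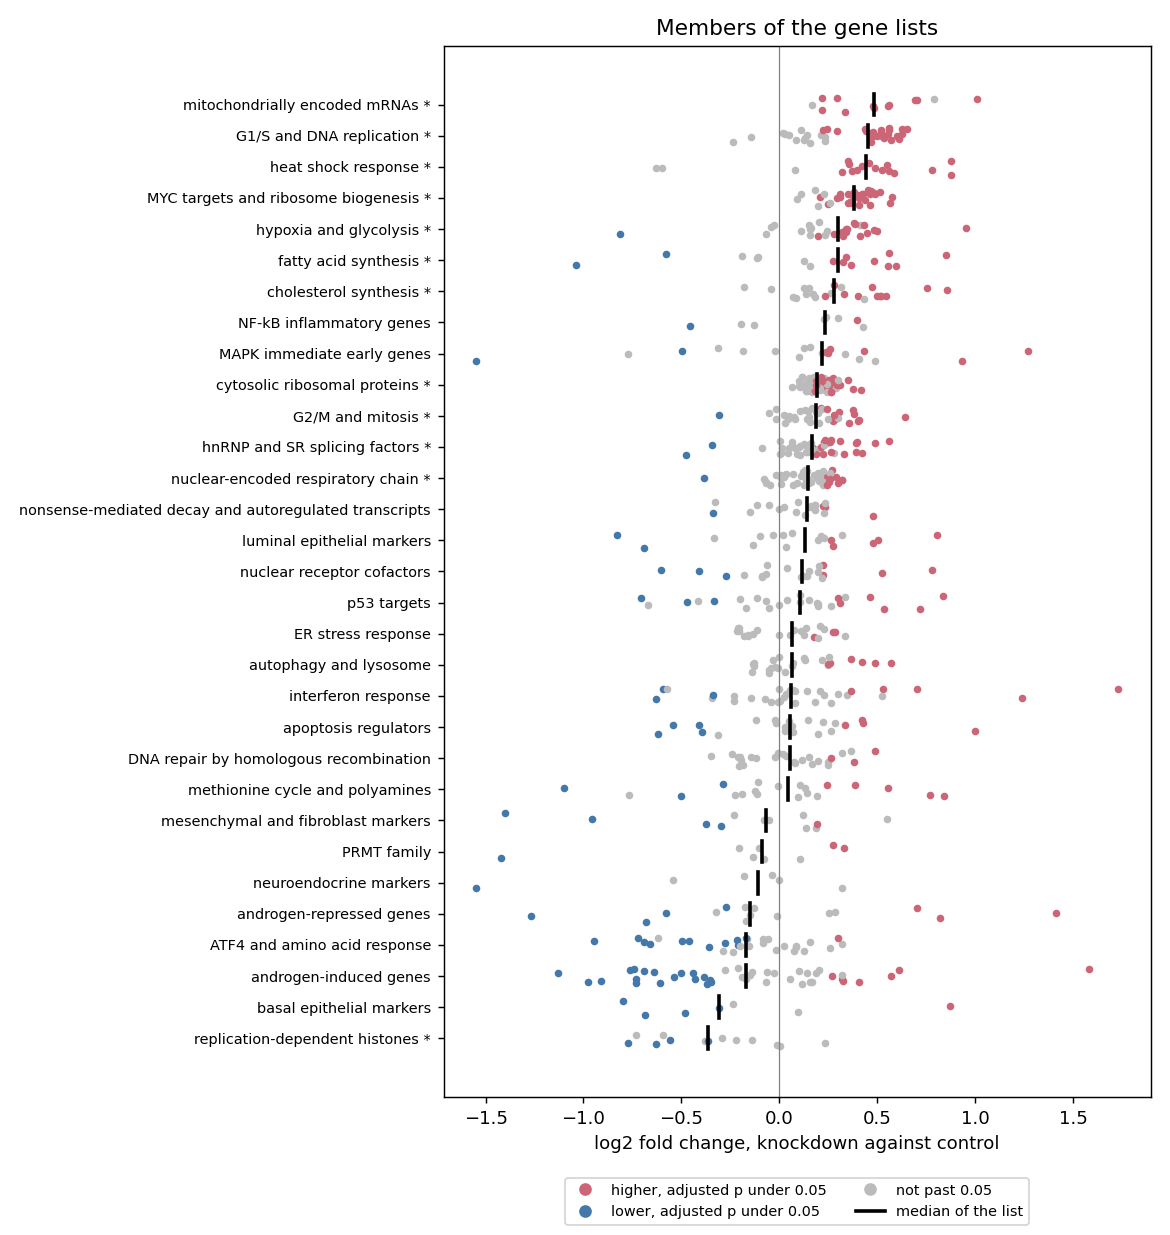
Log2 fold changes (horizontal axis, knockdown against control) of the tested members of 31 gene lists, 1 point per gene, red or blue where the edgeR adjusted p is under 0.05 and gray otherwise, with a black bar at each list's median. Lists marked with an asterisk passed camera with its preset correlation, and the medians run from 0.49 for mitochondrially encoded mRNAs to -0.36 for replication-dependent histones.

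The last question was whether the mix of transcripts from each gene changed, since arginine methylation acts on RNA-binding proteins. The mean transcript length of a gene, weighted by isoform abundance, was shorter in knockdown libraries for 37 and longer for 15 of 10942 tested genes (limma adjusted p under 0.05). The largest shortening was in the adenylyl cyclase gene ADCY1, from 6608 ± 481 to 2916 ± 237 nt (log2 change -1.18, SE 0.082, limma adjusted p = 0.0204, n = 3 each). AGAP1 (-0.85), PACS2 (-0.76), COBL (-0.74) and AFF3 (-0.73) followed. The largest lengthening was in SSH2, a cofilin phosphatase gene, from 1874 ± 72 to 3216 ± 184 nt (log2 change 0.78, SE 0.053, limma adjusted p = 0.0204, n = 3 each), then SLC39A3 (0.57), TMEM161B-AS1 (0.53), USP3-AS1 (0.50) and DEXI (0.41). Of the 37 shortened genes, 16 also fell in count and 1 rose. A shorter transcript yields fewer fragments, so these falls are not a separate result and need not mean fewer transcripts. With the replicate number as a block no gene passed. The count rested on all 6 libraries: it was 0 without control library 1, 1 without control library 2, 1 without control library 3, 12 without knockdown library 1, 0 without knockdown library 2 and 4 without knockdown library 3. The tests that gave 0 had 1024 and 998 genes at an unadjusted limma p under 0.05, against 1091 with all libraries.

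**Figure D4:**
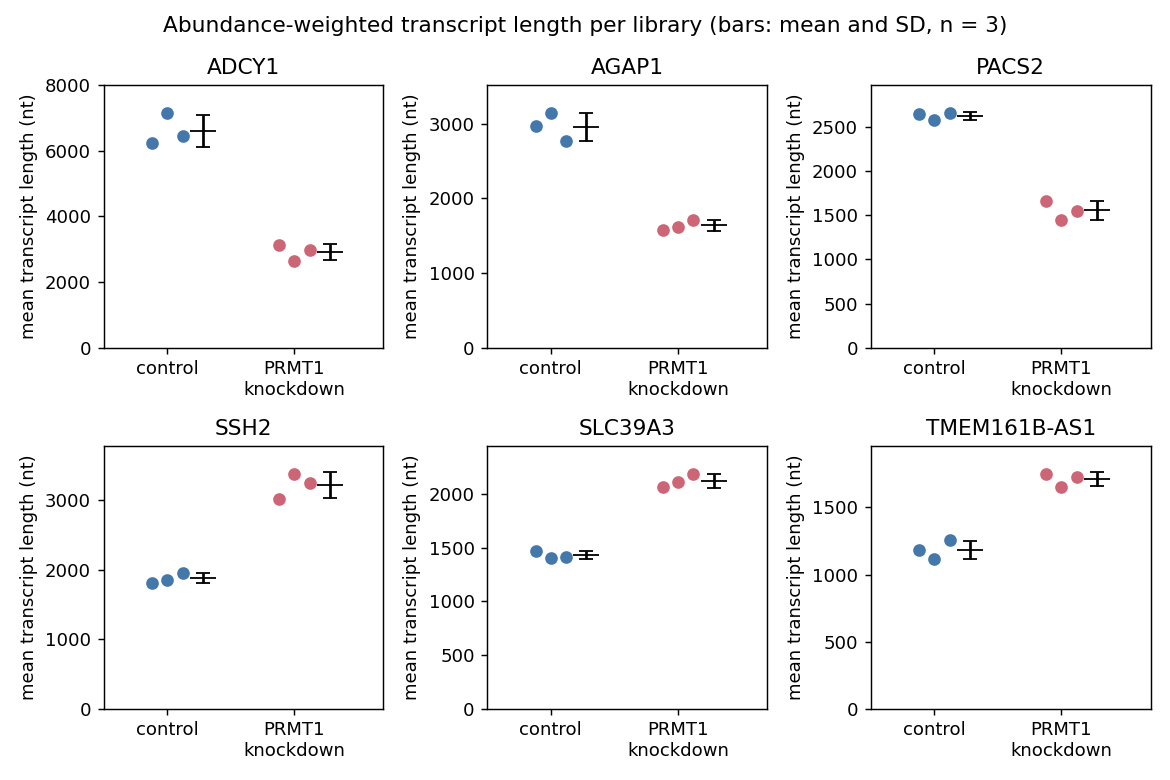
Abundance-weighted mean transcript length in nucleotides (vertical axes from 0) in each of the 3 control and 3 knockdown libraries for 6 genes, with the group mean and SD beside the points. ADCY1, AGAP1 and PACS2 are shorter in knockdown libraries (ADCY1 6608 against 2916 nt), and SSH2, SLC39A3 and TMEM161B-AS1 are longer (SSH2 1874 against 3216 nt).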

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

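PRMT1 was lower and past 0.05 under all 18 alternatives that gave it a test. Of 146 named genes besides PRMT1, 80 were past 0.05 in the same direction throughout, and of all those past it 112 never changed direction under any alternative with a value, the exception being NSD2. The fragment length covariate and the estimated correlation with that covariate or the block were chosen after seeing the data. Beyond what the construction of an alternative shows (fewer libraries, genes or a stricter threshold), the cause was not tested.

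The count of changed genes (4396, with 1939 higher and 2457 lower) was 2006 (767 higher, 1239 lower) at an adjusted p under 0.01, with 429 lower by at least 1 on the log2 scale, and 1710 (462 higher, 1248 lower) with glmTreat against 1.2-fold. With the fragment length covariate it was 7839 (4028 higher, 3811 lower), and all 4396 were among them. Other settings lost part of the 4396. Length offsets gave 3579 changed genes and lost 1186, and library size only gave 4533 and lost 1036. Limma on log2(TPM + 1) lost 2131 and on log2(TPM + 0.1) 2137, with 14008 genes tested in each. The number higher was 903 with library size only, 587 with log2(TPM + 1) and 584 with log2(TPM + 0.1). The number higher by at least 1 on the log2 scale (156) was 271 with no filter on low counts, 88 with a CPM of at least 1 in at least 3 libraries, 40 with log2(TPM + 1) and 70 with log2(TPM + 0.1), and the number lower by that size (655) was 188 with log2(TPM + 1). Leaving out 1 library gave 2386 to 5059 changed genes, 902 to 2371 higher and 1484 to 2688 lower.

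The androgen-induced list passed with fry (adjusted p = 0.00443) and cameraPR (adjusted p = 0.0287). The number of lists past 0.05 (12) was 1 with an estimated correlation, 23 with fry, and 0 with an estimated correlation and either the fragment length covariate or the replicate block.

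The count of genes with changed transcript length (52, with 15 longer and 37 shorter) was 0 with the replicate block, 0 longer and 0 shorter, where 1142 were at an unadjusted limma p under 0.05. With the fragment length covariate 9 were longer. Leaving out 1 library gave 0 to 12 genes, 0 to 2 longer and 0 to 10 shorter.

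The numbers were not taken as pairs in the main fit, because the series description states no blocking. Same-numbered libraries of the 2 groups correlated by 0.125, 0.256 and -0.125 in their deviations from the group means, which does not settle whether they were paired. With the replicate number as a block, 5003 genes changed.

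Some named values near 0 changed sign. HIST1H2AC (0.00) was negative with limma-voom (-0.0086), library size only (-0.12), upper quartile factors (-0.058), the CPM filter (-0.015), length offsets (-0.022), log2(TPM + 1) (-0.14), log2(TPM + 0.1) (-0.16), the replicate block (-0.0026), the fragment length covariate (-0.0018), and ran from -0.084 to 0.077 without 1 library. PRMT7 was -0.012 with library size only, -0.072 with log2(TPM + 1) and -0.073 with log2(TPM + 0.1). TRIM29 was -0.020 with library size only, -0.27 with length offsets, -0.29 with log2(TPM + 1) and -0.38 with log2(TPM + 0.1), and CCN1 was -0.023 with library size only, -0.045 with log2(TPM + 1) and -0.054 with log2(TPM + 0.1). With length offsets NSD2 was 0.032 and PRMT2 0.053. Leaving out 1 library gave -0.12 to 0.018 for HSD17B7, -0.16 to 0.045 for PRMT9, -0.25 to 0.032 for PRMT3 and -0.12 to 0.030 for VEGFA. The ER stress list pointed down with log2(TPM + 1) (adjusted p = 0.965) and log2(TPM + 0.1) (adjusted p = 0.969).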

Other observations

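Chosen only after the results had been seen were the grouping and scaling of gene families. So were the tests of the abundance and transcript length of long genes, early transcript ends, non-coding abundance, background size, mitochondrial scaling and doxycycline. Those of GC content, silent families and splits were chosen before their own results were seen. However, the long-gene pattern with its span limit and the non-coding pattern were themselves found in these data. The tests of GC content and silent families were therefore not planned before those patterns were seen. Protein-coding genes were grouped by the letters that open their symbols. Of 148 families with at least 10 tested members, 18 passed camera with its preset correlation and none with an estimated one. Among genes for mitochondrial ribosomal proteins, 11 of 49 MRPL and 7 of 29 MRPS genes rose and none fell. Of 37 DDX helicases 15 rose, of 31 RNA polymerase subunits (POLR) 11 rose, and of 10 UTP ribosome assembly factors 7 rose, with none lower in these 3 families, some of whose members are in the fixed lists. With library size only, 3 MRPL, 1 MRPS, 8 DDX, 5 POLR and 5 UTP genes rose and 1 MRPS, 4 DDX and 2 POLR genes fell. In the other direction, 9 of 20 collagens (COL, median log2 fold change -0.36) and 6 of 10 DHRS dehydrogenases (median -0.33) fell and none rose. The smallest adjusted p with an estimated correlation over these families was 0.671.

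Gene classes differed too. Antisense counts may hold reads of the genes they overlap, since the strand setting was not known. Counts of processed pseudogenes, which are copies of mRNAs, may hold reads shared with their parent genes. Of 793 antisense genes 223 fell and 31 rose (median log2 fold change -0.36), of 667 lincRNA genes 166 fell and 42 rose (median -0.29), and of 377 processed pseudogenes 12 fell and 33 rose (median 0.15). Protein-coding genes had a median of 0.02, with 1886 lower and 1732 higher. The median turned to -0.10 with library size only (2894 lower, 760 higher) and -0.04 with upper quartile factors (2314 lower, 1158 higher). Processed pseudogenes were 15 lower and 18 higher with library size only.

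Protein-coding genes that span at least 160 kb were lower, with 369 of 1271 falling and 89 rising (507 and 41 with library size only, 436 and 60 with upper quartile factors). Their median log2 fold change was -0.14, against 0.035 for 11400 shorter genes. Matched on CPM and transcript length, long genes still differed by -0.128, and matched on GC content by -0.183. Both lay outside the central 95% of 10000 matched draws, so these properties do not account for the whole pattern in these libraries. Draws of genes hold no spread between libraries. Long and shorter genes differed by -0.156 in the long-fragment and -0.129 in the short-fragment libraries. Single libraries lay close, with control library 2 at 0.01 and knockdown library 1 at -0.02. A hypothesis is that transcripts in long genes may end early after knockdown. Genes with shortened transcripts had a median span of 103 kb, above the 23.9 to 62.1 kb of draws matched on expression and number of transcripts. However, that set of 37 genes was not stable when a library was left out (0 to 10 shortened genes). The mean length of a gene does not tell an early end from another change of isoforms, and the draws were not matched on transcript length. Early ends were therefore not shown.

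Long non-coding genes (antisense, lincRNA and processed transcripts, with the same doubt over the 793 antisense genes) fell in 432 and rose in 92 of 1655 cases, with a median of -0.31. Coding genes matched on CPM had a median of -0.25, so most of the shift was shared with coding genes of the same abundance. The remaining difference was -0.0638, outside the matched draws. Those draws vary genes within the same 6 libraries and match on CPM alone. Their range holds no spread between libraries, and so small a difference may reflect properties that were not matched. Background RNA or DNA was weighed through 542 olfactory receptor, taste receptor, keratin-associated protein and defensin genes, taken as silent in prostate cells. Members that the cells may express were not left out, so these counts may not be background alone. Their summed CPM fell to a ratio of 0.77 (95% counting interval 0.703 to 0.844). The ratio met the prediction written before this test for a lower background, a value at or below 0.805. Values above 0.805 lie inside the interval, which covers counting error only, and coding genes matched on CPM fell as well. Meeting the prediction therefore does not set background apart from a shared fall of weakly expressed genes. At the density of those genes background would supply 1.13% of a non-coding gene's counts in the median, against a fall of 19.5%, but its density at non-coding genes was not measured, so a lower background stays open. A biological effect of PRMT1 or of doxycycline on weakly expressed genes also stays open and was not tested.

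The median of the mitochondrially encoded mRNAs ran from 0.37 to 0.503 over 4 scalings, so the choice among these did not remove the rise. All 4 scale each library to its own RNAs. They cannot tell a rise of these mRNAs from a fall of the other RNAs. Whether the rise comes from the loss of PRMT1 or from doxycycline, which acts on mitochondrial ribosomes, cannot be told apart. The reason is that 0 libraries had doxycycline without the knockdown. The median was 0.53 in the long-fragment and 0.40 in the short-fragment libraries.

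With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every split besides the real one has control and knockdown libraries on both sides. The knockdown difference then stays partly in its contrast and partly in its spread, so these splits do not measure chance. For changed genes 1 split, the real one, reached 4396, and the highest of the others gave 1 gene. For transcript length 1 split reached 52 and the others gave 0, but at an unadjusted limma p under 0.05 the real split had 1091 genes, fewer than the 1456 of the split that follows fragment length. For gene lists with the preset correlation 1 split reached 12, but the highest other gave 11. This number of lists therefore does not set the real grouping apart, nor show how many would pass without any knockdown difference. With an estimated correlation the real split gave 1 list and the others 0. The split that follows fragment length gave 0 changed genes, with 2730 at an unadjusted edgeR p under 0.05, and 4 lists.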
